A study of Arabidopsis thaliana with 24 samples.

How the data were processed

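The series holds RNA-seq of Arabidopsis thaliana whole plants. Its 24 sequenced samples fall into 4 groups, each with 3 replicates sequenced as 2 libraries. Per the labels' protocols, the Columbia (Col) wild type and the lsm4 mutant were grown on Murashige and Skoog agarose medium and harvested on day 15, whereas the C24 wild type and the lsm5 mutant (also called sad1) were grown on soil and harvested on day 30, before bolting. All grew at 22 °C in continuous light. The series' own design text gives a single growth time for all plants; the sample protocols were followed here. Libraries were made from polyA-selected RNA with a TruSeq kit, per the labels' protocols. The labels do not say that the replicates came from separate growths, so p-values measure the spread between these samples only.

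The authors deposited raw counts of reads per gene, per intron and per annotated alternative splicing (AS) bin, as whole numbers with different column totals. Per the submitters' processing notes, TopHat2 2.0.9, R 3.0.2 and edgeR 3.4.2 were used with the TAIR10 genome; the role of each, the counting tool and its strand setting are not given in the sources used here. Each deposited count column carries the tag that 2 libraries share, so a column was taken as both libraries of a replicate together, and n was 3 per group. In the counts, a gene count of 2 was more frequent than a count of 1 in every library, which is what counting both reads of a pair gives. The kit does not mark strand, so reads of overlapping or antisense genes could not be told apart. The authors' deposited tables of their own comparisons give log2 fold changes of mutant against wild type and FDR-adjusted p-values, per the file headers; they were used only for the counts credited to them. In the authors' deposited table of lsm4 AS calls, 283 bin names stood beside coordinates of another bin, so those bins were matched by coordinates. Left out were 12 per-sample columns that no sample label named, 6 lists of feature identifiers, and 1 intron row with no name, which held 11 counts in all.

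Everything from here on was computed for this re-analysis with R 4.3.3. Replicates were compared first: the chi-square per degree of freedom between replicates of a group lay between 16.0 and 148, so no pair agreed within sampling noise. Genes were tested with the edgeR 4.0.16 quasi-likelihood test on the deposited counts, with TMM scaling, the filterByExpr filter (minimum count 10) and Benjamini-Hochberg adjustment; calls are at an adjusted p under 0.05. Each mutant was compared only with its own wild type. Introns and AS bins were tested in the same way, with the log of the host gene's count in the same library as offset and a host count of at least 10 in every library. The result is called the relative intron signal, and it is not moved by a change of the whole transcript. Intron density is the count per base of an intron as a percentage of the count per base of its gene. Introns keep the numbers of the count tables, which follow the coordinates, so in genes on the minus strand they run from the 3-prime end. Expression is given as CPM, a gene's share of the counts of its library in the usual scaled unit, after TMM scaling, as mean ± SD over n = 3 libraries, and log2 fold changes are given with their standard error (SE). Where a group held 0 counts, the fold is a lower bound against a floor of 3 counts over the group; where it held 1 to 3 counts, the ratio of the summed counts, scaled for library size, is given with an exact 95% interval. Intervals and floors cover counting error only, and they treat each count as an independent read, so they are too narrow where both reads of a pair were counted.

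The difference between the mutants was tested as an interaction over all 12 count columns. Overlaps between the mutants used a one-sided Fisher's exact test over features tested in both. The mutants shared no control library. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Of the camera calls, none held with an estimated correlation. Features of raised introns were compared with those of the other tested introns by permutation tests (100000 permutations) for medians and Fisher's exact tests for bases, adjusted over 8 features. Intron sequences came from a reference of the same build: 97.7% of the tested introns in each comparison began with GT and ended with AG there, and the feature tests used those.

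The groups, the tests, 19 gene lists and the rule for naming genes were fixed before the data were examined. The lists were LSM proteins, 3 lists of clock genes, flowering time, abscisic acid (ABA), drought and cold response, heat shock, salicylic acid and immune response, jasmonate response, photosynthesis, flavonoid synthesis, mRNA decapping and decay, SR splicing factors, core spliceosome, cell cycle, and markers of senescence, roots, floral organs, and seeds and embryos. The rule took LSM4 and LSM5, then, of the called genes whose mutant and wild-type libraries did not overlap and whose higher group reached a mean of 5 CPM, the 6 with the largest rise and the 6 with the largest fall, and up to 3 genes per list with the lowest adjusted p. For introns and AS bins it took the 5 largest rises and falls with a mean count of at least 20 in the higher group, and up to 10 in genes of the lists. For the difference between mutants it took the 5 largest in each direction. Genes named outside the rule are said to be chosen after their values were seen.

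Gene depth ran from 9402839 to 52218346 counts per replicate. On simulated counts with known changes, the gene test recovered 73.8% of 4-fold and 12.5% of 2-fold changes in the lsm4 design (20557 genes), and 10.6% of 2-fold changes in the lsm5 design (19621 genes). The intron test recovered 69.1% of 4-fold changes in the lsm4 design (9948 introns) and 51.9% in the lsm5 design (6205 introns). For AS bins it recovered 72.1% and 56.9%. Of the simulated intron calls, 6.82% (3 of 44) in the lsm4 design and 13.9% (5 of 36) in the lsm5 design were false. Simulated counts were drawn independently for each feature, without a shared axis of variation or a general intron shift. The recovered and false shares may therefore not carry over to the real libraries. Alternatives included DESeq2 1.42.0, other scalings and filters, limma voom, a replicate block, each library left out in turn, and, chosen after seeing the data, 1 surrogate variable (sva 3.50.0), leaving out both libraries that stood apart, and setting the median intron change to 0.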

Results

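LSM4 and LSM5 are subunits of a cytoplasmic ring of Sm-like proteins that promotes mRNA decapping, and of a nuclear ring that binds the U6 small nuclear RNA of the spliceosome. RNA-seq was done on whole plants of the lsm4 mutant beside its Col wild type and of the lsm5 mutant beside its C24 wild type, with 3 replicates per group. Gene counts totalled 9402839, 52218346 and 26162800 in WT Col 1 to 3, and 34800709, 31480105 and 34651672 in lsm4 1 to 3. They totalled 16997209, 37194686 and 25528418 in WT C24 1 to 3, and 31532714, 34825263 and 31139275 in lsm5 1 to 3. Counts covered 33602 genes, 120717 introns and 7973 AS bins. In the lsm4 comparison the first principal component (63.1% of variance) parted the genotypes, and WT Col 1 and lsm4 2 stood apart from the other libraries on the second (20.8%). In the lsm5 comparison the first component (50.4%) parted WT C24 1 and 3 from lsm5 1 and 2, whereas WT C24 2 (score 2.15) and lsm5 3 (score -4.36) lay near 0 between them. These libraries were not alike: they lay at opposite ends of the second component (27.3%), WT C24 2 at 56.1 and lsm5 3 at -67.0.

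**Figure D1:**
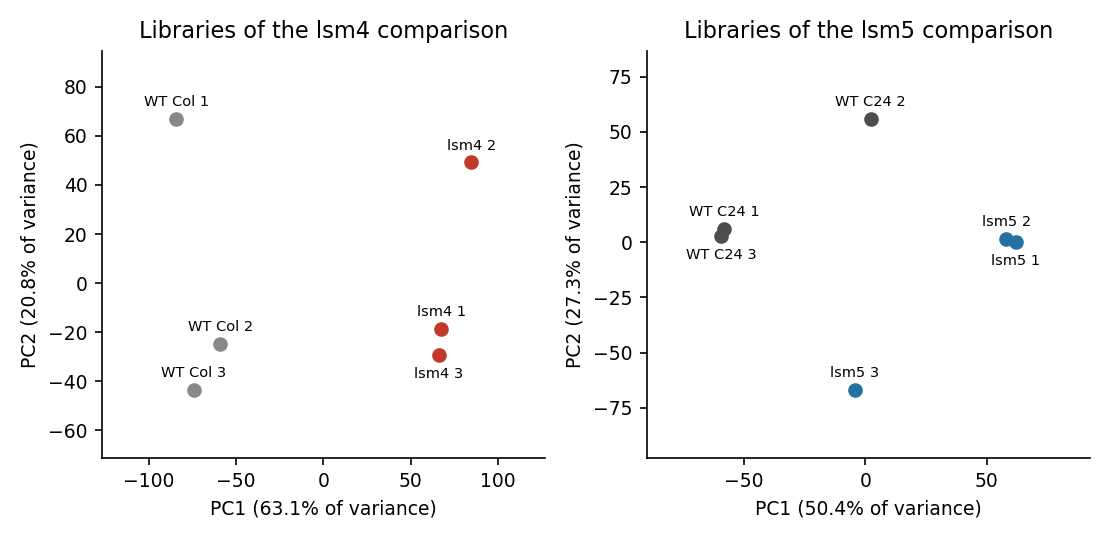
Scores of the 6 libraries of each comparison on the first 2 principal components of log2 CPM, with the share of variance on each axis; each point is a library. The genotypes separate along PC1 in the lsm4 comparison, while WT C24 2 and lsm5 3 lie near 0 on PC1 and at opposite ends of PC2 in the lsm5 comparison.

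The mutated genes were looked at first. LSM4 (AT5G27720, chromosome 5, 9815556 to 9817599, TAIR10) was higher, not lower, in the lsm4 mutant: 57.1 ± 17.3 CPM in WT Col and 352 ± 98.7 CPM in lsm4 (SD, n = 3 each). That is 6.15-fold, a log2 change of 2.62 (SE 0.30), with an edgeR quasi-likelihood adjusted p of 6.9e-04 after Benjamini-Hochberg adjustment. The 3 lsm4 libraries held 412, 238 and 405 CPM, against 42.9, 52.0 and 76.3 CPM in WT Col. LSM5 (AT5G48870, chromosome 5, 19813346 to 19814554) was at 15.8 ± 3.90 CPM in WT C24 and 12.6 ± 3.58 CPM in lsm5 (SD, n = 3 each), a difference within the spread between replicates (log2 change -0.32, SE 0.27). The total count of a gene therefore checks neither mutant label; the labels were taken as given.

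Reads within LSM4 were unevenly placed in lsm4. The annotated intron from 9816461 to 9816887, called intron 5 here, carried reads at 2.81 ± 0.544% of the gene's density in WT Col and at 51.9 ± 2.13% in lsm4 (SD, n = 3 each), with mean counts of 21.7 and 2987. Intron 6 (9816925 to 9817055) went from 18.3 ± 12.7% to 47.1 ± 1.08%, and intron 7 (9817164 to 9817281) from 6.94 ± 1.81% to 27.0 ± 2.30%. The 4 introns upstream held at most 2.08% in WT Col and at most 0.337% in lsm4. Introns 5 to 7 lie between the ends of the coding region and overlap no annotated exon in the reference. In the other accession, from WT C24 to lsm5, intron 5 went from 2.31% to 2.58%, intron 6 from 5.94% to 11.7% and intron 7 from 7.48% to 7.97%.

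**Figure D2:**
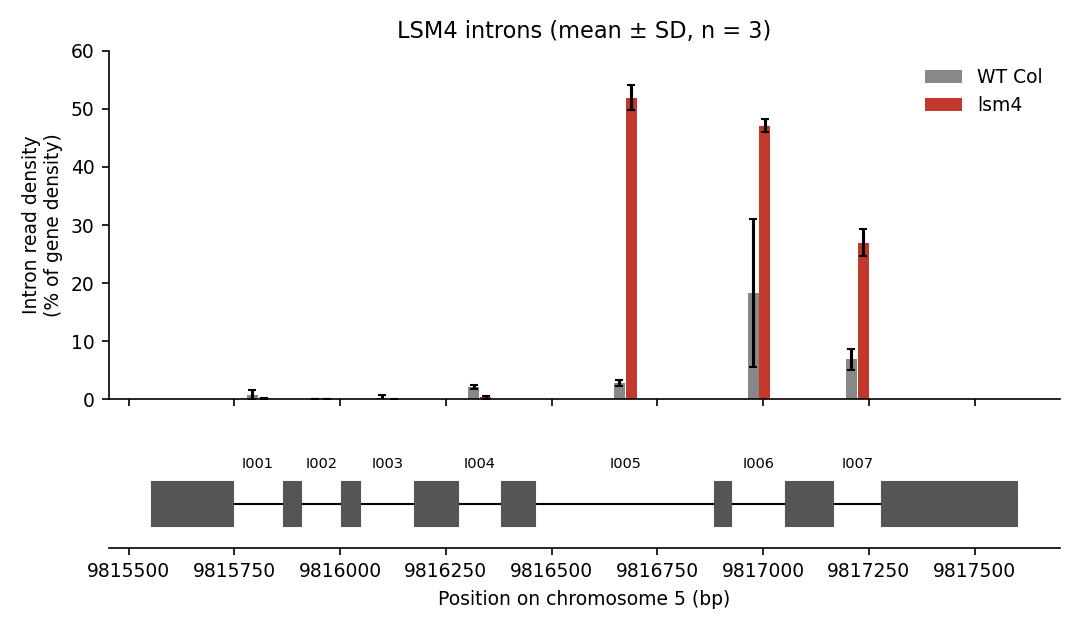
Read density in each annotated LSM4 intron as a percentage of the gene's density (bars, mean; error bars, SD; n = 3) in WT Col and lsm4, above a map of the gene on chromosome 5 with exons as boxes. Density in lsm4 is high in introns 5 to 7 (51.9% in intron 5) and at most 0.337% in introns 1 to 4.

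The first comparison asked how the lsm4 transcriptome differed from that of Col. Of 20793 genes tested, 4458 (21.4%) changed, 2230 upward and 2228 downward. Whether the called shares of the gene lists below differ from that share was not tested. The largest rises included that of AT5G24820, which had no read in WT Col and was at least 378-fold higher in lsm4 (14.1 ± 1.54 CPM). They also included that of AT1G29090, a papain-like cysteine protease gene (0.0832 ± 0.0178 to 83.7 ± 14.2 CPM, 1050-fold). The rise of the beta-amylase gene BMY1 (AT4G15210, chromosome 4, 8666338 to 8669470) was also among them. BMY1 went from 15.9 ± 8.79 to 2662 ± 619 CPM, 169-fold. AT4G28140, of the AP2/ERF transcription factor family, rose 111-fold to 32.1 ± 1.92 CPM, and AT5G35935 rose 190.5-fold to 9.87 ± 0.873 CPM. AT3G27970 had 2 reads in WT Col and 752 in lsm4, a ratio of 283 (95% interval 78.1 to 2341).

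The largest falls in lsm4 included genes of immunity. ACD6 (AT4G14400, chromosome 4, 8294446 to 8298602), a membrane protein that promotes salicylic acid signalling, fell 320-fold, from 146 ± 104 to 0.453 ± 0.138 CPM (log2 change -8.32, SE 0.74). PCC1, a small pathogen-induced protein, fell 217-fold from 649 ± 585 CPM, and its neighbour AT3G22235 fell 207-fold from 802 ± 697 CPM. The cellulase gene ATCEL2 fell 175-fold from 13.9 ± 6.22 CPM, the bHLH gene ATNIG1 169-fold from 11.9 ± 5.64 CPM, and AT5G03350, of the legume lectin family, 106-fold from 112 ± 103 CPM (all SD, n = 3). The wild-type level of some of these genes varied widely: PCC1 stood at 517, 141 and 1288 CPM in WT Col 1 to 3, all above the lsm4 libraries at 2.95, 3.61 and 2.36 CPM. Of 17 tested members of the salicylic acid and immune list, 5 fell and 2 rose in lsm4, as they did when adjusted over the list alone. Besides ACD6, the members PR1, PR2, WRKY70 and ICS1 (named after their values were seen) fell, and PR5 (14.9 ± 8.01 to 47.6 ± 6.15 CPM) and the camalexin synthesis gene CYP71A13 (19.9 ± 3.14 to 43.3 ± 9.80 CPM) rose. PR1 lay at 15.9, 6.82 and 639 CPM in WT Col 1 to 3, so that its mean rests on WT Col 3, and the libraries of the genotypes overlapped for PR1 and WRKY70. The list did not pass the set test (camera adjusted p = 0.45); it passed downward only without WT Col 2 (adjusted p = 0.021), with a range from 0.021 to 0.89 over its alternatives.

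Most jasmonate genes of the list rose in lsm4. Of 13 tested members 9 rose and 1 fell, as they did when adjusted over the list alone. AOC1, an enzyme of jasmonate synthesis, rose 4.83-fold (52.6 ± 12.4 to 254 ± 11.6 CPM), and the repressors of jasmonate signalling JAZ10 and JAZ5 rose by a log2 change of 2.83 (SE 0.39) and by 3.93-fold (3.01 ± 0.251 to 11.9 ± 0.688 CPM; SD, n = 3). AOS rose too (log2 change 0.92, SE 0.18), and the defensin gene PDF1.2A was the member that fell (log2 change -2.04, SE 0.59). The list passed camera (adjusted p = 6.5e-05); with an estimated correlation its p was 0.031 and its adjusted p = 0.59, and fry gave an adjusted p = 0.0076. AOC1 and AOC2 are close paralogs in tandem, and their reads may be split unevenly.

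Of 24 tested photosynthesis genes, 10 fell and none rose in lsm4, and 20 fell when adjusted over the list alone. The light-harvesting gene LHCB1.2 fell 6.55-fold (10116 ± 1747 to 1545 ± 359 CPM) and LHCB1.3 fell 3.58-fold (31601 ± 2715 to 8823 ± 3005 CPM), with the reservation that the LHCB1 genes are near-identical copies. PORB, an enzyme of chlorophyll synthesis, fell 3.66-fold (607 ± 257 to 166 ± 24.3 CPM; SD, n = 3). The list passed camera (adjusted p = 1.4e-07), but with an estimated correlation its p was 0.18 and its adjusted p = 0.87. Of 9 tested root markers, 4 fell and none rose, and 6 fell when adjusted over the list alone (camera adjusted p = 0.0049; with an estimated correlation p = 0.17, adjusted p = 0.87). Those that fell included RHD6 of root hairs (4.05 ± 1.53 to 0.706 ± 0.249 CPM), CASP1 of the endodermis (17.0 ± 5.34 to 5.76 ± 2.04 CPM) and the iron transporter IRT1 (134 ± 37.9 to 62.6 ± 9.10 CPM). IRT1 lost its call without lsm4 1 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.055, the highest over its alternatives; the lowest was 1.8e-04).

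ABA, drought and cold genes went both ways in lsm4, 5 up and 7 down of 32 tested (6 up and 7 down when adjusted over the list alone; camera adjusted p = 0.69). COR15B fell by a log2 change of -3.97 (113 ± 64.1 to 7.18 ± 1.37 CPM), GOLS2 of raffinose synthesis by one of -2.58 (20.4 ± 6.96 to 3.42 ± 0.260 CPM), and KIN1, which has a close copy in KIN2, by one of -1.66 (288 ± 46.4 to 90.9 ± 8.62 CPM; SD, n = 3). Members that rose, named after their values were seen, were COR47 (log2 change 2.08, SE 0.33), ERD10, ERD1, RD26 and RD29A. Of 12 heat shock genes 4 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.69), among them HSP70 (34.4 ± 2.73 to 63.7 ± 8.82 CPM) and HSP18.2 (3.30 ± 1.25 to 13.2 ± 6.47 CPM) upward and ROF2 (4.44 ± 0.312 to 2.23 ± 0.245 CPM) downward. HSP18.2 lost its call without WT Col 2 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.055, the highest over its alternatives; the lowest was 8.2e-05). ROF2 lost its call in 5 of 6 fits that left out a library, the exception being the fit without WT Col 1.

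Of 18 flowering time genes, 1 rose and 4 fell in lsm4 (2 and 4 when adjusted over the list alone; camera adjusted p = 0.46). The floral repressor FLC (AT5G10140, chromosome 5, 3173497 to 3179448) fell 11.5-fold from a low level (1.52 ± 0.527 to 0.130 ± 0.0799 CPM), SPL9 2.54-fold (12.9 ± 2.19 to 5.04 ± 1.33 CPM) and MAF5 3.04-fold (1.88 ± 0.195 to 0.611 ± 0.129 CPM). MAF5 lost its call without WT Col 2 or lsm4 1. The others, named after their values were seen, were SPL5, which fell, and MAF3, which rose. Of 14 flavonoid genes 3 fell and 1 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.73): MYB111 fell 6.10-fold (4.28 ± 0.798 to 0.702 ± 0.140 CPM) and FLS1 2.76-fold (64.8 ± 11.2 to 23.5 ± 5.20 CPM), while the anthocyanin regulator PAP2 had 1 read in WT Col and 84 in lsm4, a ratio of 63.2 (95% interval 11.04 to 2526). Of 15 cell cycle genes 5 rose and none fell (7 rose when adjusted over the list alone; camera adjusted p = 0.060), led by the replication factor MCM5 (22.5 ± 2.90 to 53.6 ± 9.33 CPM). The list passed camera without WT Col 1 (adjusted p = 0.016) or lsm4 3 (adjusted p = 0.034) and, barely, with 1 surrogate variable, with a range from 0.016 to 0.89 over its alternatives. CDKB2-2 and CYCB1-1 also rose (log2 changes 0.92, SE 0.23, and 1.04, SE 0.29), but CDKB2-2 lost its call without WT Col 2, WT Col 3 or lsm4 1, and CYCB1-1 when any library but lsm4 3 was left out.

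Few genes of the clock and of RNA processing changed in level in lsm4. Of 11 morning or day phased clock genes none changed. Among 12 evening phased ones JMJ30 fell (48.2 ± 2.79 to 27.9 ± 6.95 CPM) and PRR5 rose (18.9 ± 8.62 to 36.2 ± 0.174 CPM), and among 8 others CHE fell (45.3 ± 8.09 to 14.6 ± 5.39 CPM). JMJ30 and PRR5 each lost their call in 5 of 6 fits that left out a library, all but the fit without lsm4 2 for JMJ30 and without WT Col 1 for PRR5; adjusted over the list alone, none of the evening genes and 1 of the others passed. No call was made among 11 genes of mRNA decapping and decay, 20 SR splicing factors and 17 core spliceosome genes, over all genes or adjusted over the list alone. Of 11 LSM genes, LSM4 and LSM3A rose in both ways of adjusting; LSM3A (11.5 ± 2.35 to 21.4 ± 4.46 CPM) lost its call without WT Col 2, WT Col 3, lsm4 2 or lsm4 3. The camera adjusted p of these 7 lists lay between 0.45 and 0.82. SAG13 of senescence (4.48 ± 2.63 to 15.1 ± 2.09 CPM), 1 of 4 tested in its list, rose, as did SEP3, 1 of 3 tested floral markers (0.183 ± 0.157 to 2.26 ± 0.747 CPM). Of 3 tested seed genes SESA1 rose (0.0429 ± 0.0743 to 1.32 ± 0.545 CPM) and CRA1, with no read in lsm4, was at least 20.4-fold lower. Adjusted over the list alone, the counts of these 3 lists were the same but for SESA2, which then also fell; their camera adjusted p lay between 0.45 and 0.85.

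The lsm4 gene counts rest in part on single libraries. Without lsm4 1 the test called 2704 genes and without WT Col 2 it called 2866. Of 47 named and called genes, 37 kept their call in every setting tried, and none of them changed direction. HSP70 lost its call only where an absolute log2 change of at least 1 was required. The authors' deposited tables list 6578 genes for lsm4, at an FDR of at most 0.104; of these, 6350 were tested here, all with the same direction, and 4420 were called.

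**Figure D3:**
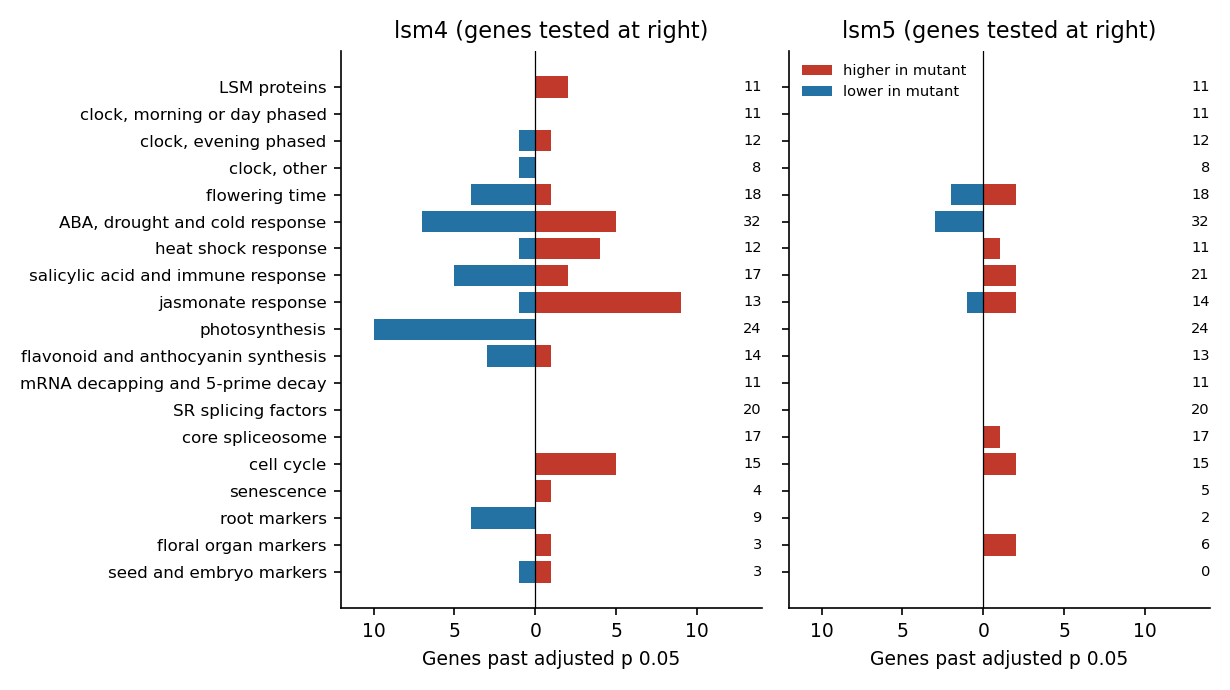
Number of genes of each fixed list that were higher (red, to the right) or lower (blue, to the left) in the mutant at an adjusted p under 0.05 in the lsm4 (left) and lsm5 (right) comparison, with the number of tested members at the right edge. In lsm4, 9 of 13 jasmonate genes were higher and 10 of 24 photosynthesis genes lower.

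Intron reads made up a larger share of gene reads in lsm4. They stood at 1.84 ± 0.0601% of gene counts in WT Col and 2.85 ± 0.123% in lsm4 (SD, n = 3 each), a ratio of 1.55, with every lsm4 library above every WT Col library (exact permutation test, two-sided, p = 0.1, the smallest this design allows). Relative intron signal rose for most introns: the median log2 change of 11439 tested introns was 0.65, and 81.8% were above 0. Of these introns 2031 rose, in 1598 of 6045 host genes, and 34 fell. Measured against the median intron, 570 introns differed, of which 72.8% were higher, compared with 98.4% of the calls made without that centring. A minimum mean count of 30 left 2977 introns, of which 507 were called. Without WT Col 2 the test called 956 introns, and without lsm4 1 it called 1115. The authors' deposited tables list 3050 higher and 1165 lower introns for lsm4, at an FDR of at most 0.150. Of these, 2001 were tested here, 1876 with the same direction, and 943 were called. The calls were uneven: 916 of 1169 tested introns from the table labelled up in lsm4, but 27 of 832 from that labelled down. Those with the same direction here were 1160 and 716. The authors' lower introns were thus mostly not called here.

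**Figure D4:**
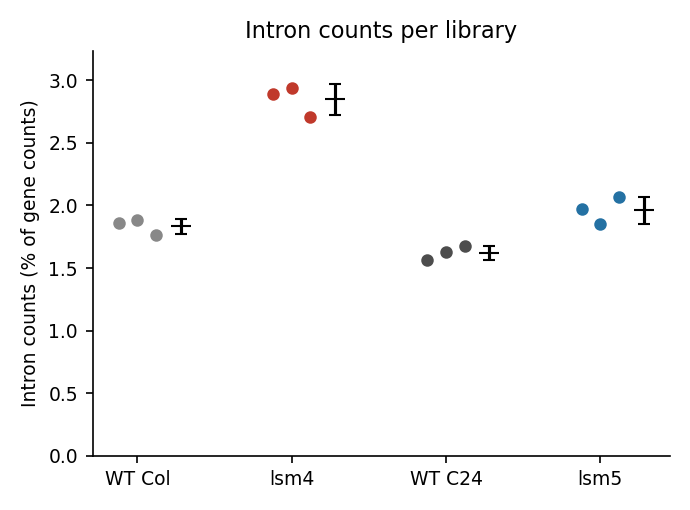
Intron counts as a percentage of gene counts in each library (points), with the mean and SD of each group beside them (n = 3). The lsm4 libraries lie between 2.71% and 2.94%, above WT Col at 1.77% to 1.88%.

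The largest fitted rises were in introns with no read in WT Col, where the fitted size depends on the prior count. Their lower bounds cannot rank them against introns with reads in both groups, such as intron 5 of LSM4 (17.9-fold). Intron 1 of SZF2, a zinc finger gene, on the side of the 5-prime UTR (chromosome 2, 16772254 to 16772528), reached 9.98 ± 1.57% of gene density in lsm4, at least 13.7-fold higher. Intron 3 of CHUP1, needed for chloroplast positioning (chromosome 3, 9354315 to 9354382), reached 18.8 ± 8.43%, at least 20.4-fold higher. Intron 3 of AT4G19420 (chromosome 4, 10588092 to 10588210) reached 44.9 ± 13.6%, at least 9.56-fold higher. Introns 2 and 3 of AT4G24430, both within its coding region, rose too, at least 2.76-fold and 3.32-fold. Both lost their call without WT Col 2, and intron 3 overlaps an annotated exon. Among the fixed lists, introns rose in genes whose total level was not called: intron 7 of the decapping gene DCP1 (chromosome 1, 2640246 to 2640310; 2.58 ± 2.57 to 47.5 ± 5.40%), intron 3 of DCP5 (chromosome 1, 9025312 to 9025439; 2.27 ± 1.98 to 22.0 ± 8.50%), intron 1 of the exonuclease gene XRN4 (no read in WT Col, 4.47 ± 2.26% in lsm4, at least 15.4-fold higher, in part over an annotated exon) and intron 9 of the splicing factor U2AF65A (2.45 ± 1.54 to 16.9 ± 3.17%). Others lay in RCA (intron 4, 0.191 ± 0.0166 to 1.35 ± 0.0302%), KIN2 (intron 2, 1.32 ± 0.228 to 5.63 ± 0.628%), CHS (intron 1, 0.395 ± 0.215 to 3.66 ± 1.47%) and DFR (intron 2, 5.17 ± 1.72 to 30.0 ± 1.16%; SD, n = 3).

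By list, 6 of 11 tested introns of decapping and decay genes rose, in 3 genes; 19 of 72 introns of SR splicing factors rose, in 11 genes; and 8 of 32 introns of core spliceosome genes rose, in 6 genes. In the ABA, drought and cold list 9 of 49 rose. Over all introns tested, 17.8% rose. Whether these lists differ from that share was not tested. The introns that fell furthest were intron 1 of CYP71A13 (27.8 ± 5.23 to 5.56 ± 3.53% of gene density), intron 4 of ATSRL1 (5.38-fold), which lies inside an annotated exon of the reference, intron 3 of AT1G53250 (5.14-fold), intron 10 of TGA4, on the side of the 5-prime UTR and in part over an annotated exon (4.67 ± 1.81 to 1.23 ± 0.336%) and intron 10 of ATSPT1 (157 ± 29.4 to 45.5 ± 21.2%). That of AT1G53250 lost its call when any library but lsm4 1 was left out, and those of TGA4 and ATSPT1 without WT Col 2.

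**Figure D5:**
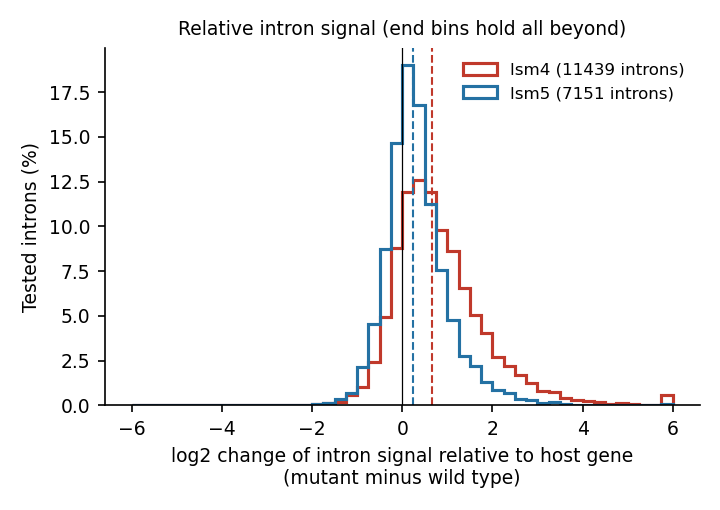
Distribution of the log2 change in relative intron signal over the introns tested in each comparison, as a percentage of tested introns per bin of 0.25; dashed lines mark the medians and the end bins hold all values beyond them. The median is 0.65 in lsm4 and 0.24 in lsm5.

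The splice sites of raised introns differed from those of the others. Among introns that start with GT and end with AG, 1999 raised ones were compared with 9182 others. G at position +5 of the intron, a base of the 5-prime splice site, was found in 59.6% of the raised introns and 47.0% of the others (Fisher's exact test, two-sided, adjusted p = 1.3e-23). G at the last base of the upstream exon was less frequent (74.5% against 81.2%, adjusted p = 1.4e-10), T at +6 more frequent (56.5% against 49.5%), and so were A at +3 (66.7% against 62.4%), A at +4 (54.7% against 51.1%) and C at position -3 of the acceptor (68.0% against 64.3%). Raised introns were shorter, with a median of 106 bases against 116 (permutation test, two-sided, adjusted p = 0.0021), and their median GC content was the same, 33.3% (adjusted p = 1). Introns are not independent replicates. Within the highest and within the lowest tertile of intron count 4 of the 8 features passed, G at +5 (55.1% against 46.2%, and 61.0% against 48.7%) among them; length, A at +4 and C at position -3 of the acceptor passed in neither. In the middle tertile 6 passed, these 3 among them, but A at +3 did not (63.3% against 63.1%). A at +4 did not pass with DESeq2 calls.

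Of 3549 AS bins tested in lsm4, 13 rose and none fell (264 and 65 at an unadjusted p under 0.05; DESeq2 called 51). With library sizes in place of the host gene offset 212 were called, of which 73.1% were higher, compared with 100% of the 13. By type, 6 of 1011 intron retention bins, 4 of 540 alternative 5-prime sites, 1 of 1131 alternative 3-prime sites, 2 of 561 bins with several event types and 0 of 306 skipped exons were called; of the skipped exons, 7 were higher and 11 lower at an unadjusted p under 0.05. The retained intron in RCD1 (chromosome 1, 11615740 to 11615831) rose 6.06-fold (log2 change 2.60, SE 0.40) relative to its gene, that in BAT1 (chromosome 2, 104294 to 104361) went from 23.0 ± 11.5 to 159 ± 12.4% of gene density, and that in the expansin gene EXP1 (chromosome 1, 26141920 to 26142008) from 0.684 ± 0.970 to 12.6 ± 1.75%. An alternative 3-prime site in the glutamine synthetase gene ATGSR2 went from 0.485 ± 0.445 to 7.70 ± 2.37%. A 4-base stretch at an alternative 5-prime site of NOI held 2 reads in WT Col and 113 in lsm4, a ratio to its host of 28.03 (95% interval 7.58 to 234). The count fell to 0 without WT Col 3, lsm4 1 or lsm4 3 and to 1 without WT Col 2, where the bin of EXP1 kept its call. The authors' deposited table lists 286 higher and 78 lower AS bins for lsm4, at an FDR of at most 0.150. Of these 364 bins, 242 were tested here, 240 with the same direction, and 9 were called.

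The second comparison asked the same of lsm5 and its C24 wild type. Of 19819 genes tested 300 rose and 186 fell. AT2G15555 (chromosome 2, 6785904 to 6786976) rose 413-fold, from 0.156 ± 0.0895 to 71.0 ± 3.30 CPM, with a log2 change of 8.69 (SE 0.32). AT5G41830 rose 63.5-fold (0.153 ± 0.154 to 10.8 ± 2.72 CPM), AT2G20870 30.7-fold (0.422 ± 0.193 to 13.5 ± 4.49 CPM), AT2G04135 21.9-fold (0.267 ± 0.238 to 6.58 ± 1.41 CPM), the polygalacturonase gene ADPG1 15.1-fold (0.334 ± 0.158 to 5.38 ± 3.12 CPM) and Sadhu4-2, a retroelement, 14.5-fold (0.763 ± 0.456 to 11.6 ± 3.72 CPM; all SD, n = 3).

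Falls in lsm5 were ranked among called genes whose groups did not overlap and whose higher group reached a mean of 5 CPM. The largest of these were in PSBA, the chloroplast gene of the D1 protein of photosystem II (36.4 ± 19.9 to 3.53 ± 1.74 CPM, 10.3-fold), in the mitochondrial dicarboxylate carrier gene DIC2 (101 ± 48.6 to 10.99 ± 0.595 CPM, 9.20-fold) and in the iron superoxide dismutase gene FSD1 (50.5 ± 23.3 to 5.51 ± 3.91 CPM, 9.16-fold). PHI-1 fell 8.93-fold from 96.5 ± 54.2 CPM, AT1G65486 8.44-fold from 10.5 ± 2.70 CPM and AT4G36850 7.15-fold from 95.4 ± 29.4 CPM (SD, n = 3). PSBA is read from the organelle, and genes of the organelles together took 2.93, 1.06 and 2.27% of counts in WT C24 1 to 3 and 0.244, 0.806 and 0.149% in lsm5 1 to 3. Of 29 named and called genes in lsm5, 4 kept their call in every setting and 25 lost it in at least 1. ADPG1 and PSBA lost theirs without WT C24 1, WT C24 3, lsm5 1 or lsm5 2, FSD1 without WT C24 1, WT C24 3 or lsm5 2, PHI-1 without WT C24 3, lsm5 1 or lsm5 2, AT2G04135 and AT4G36850 without WT C24 3 or lsm5 2, Sadhu4-2 and AT1G65486 without WT C24 3, and DIC2 without lsm5 2.

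Flowering genes were examined in lsm5, which was harvested before bolting. Of 18 tested flowering time genes 2 rose and 2 fell (3 and 6 when adjusted over the list alone; camera adjusted p = 0.93). FLC fell 2.35-fold (66.7 ± 8.15 to 28.3 ± 4.45 CPM) and TEM2, a repressor of FT, 2.42-fold (159 ± 47.5 to 65.6 ± 3.85 CPM). FUL rose 3.02-fold (1.43 ± 0.544 to 4.39 ± 0.398 CPM), as did FT, the mobile flowering signal, named after its values were seen (0.135 ± 0.185 to 2.01 ± 0.909 CPM, log2 change 3.78, SE 0.79). Of 6 tested floral organ markers 2 rose and none fell (3 rose when adjusted over the list alone). AP1 had 1 read in WT C24 and 221 in lsm5, a ratio of 169 (95% interval 30.1 to 6718), and AP3 had 1 and 61, a ratio of 46.7 (95% interval 8.08 to 1876). SEP2 was at 0.0607 ± 0.105 and 0.989 ± 0.481 CPM and did not pass. The list passed camera (adjusted p = 4.3e-05); with an estimated correlation its p was 0.034 and its adjusted p = 0.58, and fry gave an adjusted p = 0.0090. FLC and AP3 lost their calls without WT C24 1, WT C24 3, lsm5 1 or lsm5 2, TEM2 without WT C24 2, WT C24 3, lsm5 1 or lsm5 2, and FUL when any library but lsm5 3 was left out.

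Stress genes were called in small numbers in lsm5, where 2.45% of all tested genes were called. Whether the called shares of these lists differ from that was not tested. Of 32 ABA, drought and cold genes 3 fell and none rose (4 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.92): the proline synthesis gene P5CS1 (210 ± 2.83 to 93.2 ± 13.8 CPM), and the cold response regulators CBF2 (2.43 ± 0.880 to 0.219 ± 0.0569 CPM) and CBF1, which held 44 reads in WT C24 and 2 in lsm5, 28.7-fold lower (95% interval 7.49 to 245). CBF1 and CBF2 are close paralogs. In the salicylic acid and immune list 2 of 21 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.88), both of camalexin synthesis: PAD3 (72.9 ± 6.76 to 186 ± 26.8 CPM) and CYP71A13 (123 ± 32.3 to 377 ± 103 CPM). Of 14 jasmonate genes 2 rose and 1 fell (2 and 2 when adjusted over the list alone; camera adjusted p = 0.88). PDF1.2A (log2 change 3.09, SE 0.52) and VSP1 (4.86 ± 2.36 to 26.6 ± 14.3 CPM) rose and AOS fell (81.1 ± 5.30 to 44.4 ± 2.70 CPM). HSP17.4 (1.08 ± 0.298 to 5.61 ± 2.00 CPM) rose, 1 of 11 heat shock genes in both ways of adjusting (camera adjusted p = 0.88). P5CS1, CYP71A13, PDF1.2A and VSP1 lost their calls without WT C24 1, WT C24 3, lsm5 1 or lsm5 2; PAD3 and HSP17.4 without WT C24 1, WT C24 3 or lsm5 2; CBF2 without WT C24 3, lsm5 1 or lsm5 2; CBF1 and AOS when any library but lsm5 3 was left out.

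The core spliceosome list passed camera upward in lsm5 (adjusted p = 8.8e-04; with an estimated correlation p = 0.13, adjusted p = 0.96), with 1 of 17 genes called in both ways of adjusting, PRP3 (42.8 ± 12.5 to 120.0 ± 31.0 CPM). The cell cycle list did so too (adjusted p = 0.0024; with an estimated correlation p = 0.18, adjusted p = 0.96): 2 of 15 rose, and 4 when adjusted over the list alone, with CYCB1-1 at 2.86 ± 0.264 and 9.35 ± 1.00 CPM and MCM5 at 12.6 ± 0.537 and 24.3 ± 2.77 CPM. This list lost its call without WT C24 2 (adjusted p = 0.095) or lsm5 3 (adjusted p = 0.068), and SR splicing factors, at a camera adjusted p of 0.060, gained one upward without WT C24 2 (adjusted p = 0.0068) or lsm5 3 (adjusted p = 1.9e-04) and with a replicate block (adjusted p = 0.045). Over their alternatives the adjusted p ran from 2.7e-04 to 0.96 for the cell cycle list and from 1.9e-04 to 0.96 for SR splicing factors. PRP3 and CYCB1-1 lost their calls without WT C24 1, WT C24 3, lsm5 1 or lsm5 2, and MCM5 when any library but lsm5 3 was left out. No gene was called in the other lists: LSM proteins, the 3 clock lists, photosynthesis, flavonoid synthesis, decapping and decay, SR splicing factors, senescence, and root markers, of which 2 were tested; no seed marker was tested. Adjusted over the list alone, 1 senescence gene and both root markers fell. The camera adjusted p of the lists without a call other than SR splicing factors lay between 0.35 and 0.88, and camera was not run for root markers.

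The lsm5 gene counts depended on single libraries more than those of lsm4. They fell to 54 without WT C24 1, 23 without WT C24 3, 98 without lsm5 1 and 37 without lsm5 2, and rose to 2042 without lsm5 3. The 2 libraries near 0 on the first component, WT C24 2 and lsm5 3, come 1 from each genotype; leaving out both, a choice made after seeing the data that widens the gap between groups by construction, gave 7901 genes. The authors' deposited tables list 1845 genes for lsm5, of which 1748 were tested here, all with the same direction, and 486 were called.

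Intron reads took 1.62 ± 0.0551% of gene counts in WT C24 and 1.96 ± 0.109% in lsm5 (SD, n = 3 each), a ratio of 1.21, again with every mutant library above every wild-type library (exact permutation test, two-sided, p = 0.1, the smallest this design allows). The median log2 change over 7151 introns was 0.24, and 68.6% were above 0. Of these introns 37 rose, in 36 host genes, and 1 fell. Intron 2 of GASA1, a gibberellin-regulated gene (chromosome 1, 28442117 to 28442209), went from 0.664 ± 0.147 to 18.23 ± 12.5% of gene density, and intron 1 of PSBQA, of photosystem II, from 0.222 ± 0.129 to 5.06 ± 4.03%. Intron 8 of the carbonic anhydrase gene CA1 went from 0.0218 ± 0.00498 to 1.75 ± 2.34%, with mean counts of 1.33 and 119. Intron 13 of AT2G27350 held 1 read in WT C24 and 200 in lsm5, a ratio to its host of 143 (95% interval 25.3 to 5663). Its density in lsm5 was 11.9 ± 13.2%, an SD above the mean, so the reads came unevenly from the libraries. Intron 24 of HIT1, inside an annotated exon of the reference, held 1 and 62 reads, a ratio of 46.4 (95% interval 8.02 to 1860), with a density of 21.7 ± 7.48% in lsm5. In the fixed lists, intron 2 of WRKY70 (0.920 ± 0.0152 to 5.69 ± 1.11%) and intron 4 of RCA (0.146 ± 0.0260 to 0.591 ± 0.191%) rose, and intron 11 of the splicing factor gene PRP39 was the one that fell (38.6 ± 17.2 to 5.82 ± 1.96%). Each of these introns lost its call without WT C24 1 or WT C24 3, all but that of GASA1 also without lsm5 1, and those of CA1, HIT1, WRKY70, RCA and PRP39 also without lsm5 2.

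These intron counts fell to 0 without WT C24 1 or WT C24 3, to 4 without lsm5 1 and to 3 without lsm5 2; they rose to 99 without WT C24 2 and 184 without lsm5 3. Measured against the median intron, 7 were called, of which 85.7% were higher, compared with 97.4% of the 38. No splice-site feature of the 36 raised GT-AG introns passed the test. G at +5 stood in 61.1% of them and 46.6% of the 6953 others (Fisher's exact test, two-sided, adjusted p = 0.38). Among the 143 GT-AG introns raised by DESeq2, G at +5 was more frequent than in the others (61.5% against 46.4%; same test, adjusted p = 0.0014). G at the last base of the upstream exon was less frequent there (68.5% against 82.6%; same test, adjusted p = 4.3e-04). None of 2932 AS bins was called in lsm5 by edgeR (97 higher and 40 lower at an unadjusted p under 0.05; DESeq2 called 16). In the simulated data of this design the test recovered 56.9% of 4-fold changes in AS bins (2740 bins), so smaller changes were largely out of reach. The authors' deposited table lists 57 AS bins for lsm5, at an FDR of at most 0.140. Of these, 36 were tested here, all with the same direction, and none was called.

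Features called in both mutants were then counted. Of 231 genes higher in lsm5 that were tested in both, 92 were among the 2001 higher in lsm4, against 24.2 for independent lists (one-sided Fisher's exact test, p = 7.2e-32). Of 181 lower genes 40 were shared with the 1972 lower in lsm4, against 18.7 (one-sided Fisher's exact test, p = 2.5e-06). Of 34 introns raised in lsm5, 27 were among the 856 raised in lsm4, against 4.96 (one-sided Fisher's exact test, p = 3.7e-17). Of the 34, 33 had the same sign in lsm4, where 81.8% of all tested introns were above 0. These exact tests treat genes and introns as independent and equally likely to be called, and neither was checked. The 15 and 1 lower introns shared none. Intron 4 of RCA upward and the transcripts of CYP71A13, MCM5 and CYCB1-1 upward, and of P5CS1 and FLC downward, were among those called in both. The shared counts depended on the lsm5 calls. Shared higher genes were 11 without WT C24 1, 8 without WT C24 3, 23 without lsm5 1, 6 without lsm5 2 and 230 without lsm5 3. By the same exact test, the lower overlap no longer passed without WT C24 1 (3 shared, p = 0.34), WT C24 3 (0 shared) or lsm5 2 (2 shared, p = 0.12), and counted 5 without lsm5 1 and 129 without lsm5 3. By the same exact test, the intron overlap fell to 0 without WT C24 1 or WT C24 3 and to 2 without lsm5 1 (p = 0.057) or lsm5 2 (p = 0.059), and rose to 59 without WT C24 2 and 109 without lsm5 3.

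The difference between the effects of the mutants was tested directly over all libraries. It passed in 2265 of 21588 genes, with the lsm5 effect above the lsm4 effect in 1097 and below it in 1168. Mutant, accession, age and medium differ together in this contrast, so their parts in it cannot be told apart. Differences were ranked among genes past the threshold with a mean of at least 5 CPM in 1 or more groups. The largest positive ones were in AT2G20870 (log2 difference 9.07, SE 0.80), the cytochrome P450 gene CYP706A3 (8.86, SE 0.86), ACD6 (8.21, SE 0.74), ATCEL2 (8.18, SE 0.73) and PCC1 (7.64, SE 0.88). The largest negative ones were in AT5G24820 (-10.31, SE 2.68), AT1G29090 (-9.48, SE 1.21), AT4G28140 (-7.92, SE 0.44), AT3G27970 (-6.95, SE 1.54) and M17 (-6.91, SE 1.23), where levels near 0 in 1 or more groups make the fitted size depend on the prior count. The count was 1368 without lsm5 1, 1381 without WT C24 3 and 1507 without lsm5 2.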

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

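The tests of exchanged labels and of the general rise at LSM4, and the way the axis of variation within groups was defined, were chosen only after the results were seen. Groups of 3 are too small for a test of outlying libraries, so the results here are those for which the effect of lsm5 against C24 differed from the effect of lsm4 against Col in the edgeR quasi-likelihood test of the interaction. Of 122 named genes tested, 43 differed, 18 with a negative and 25 with a positive difference; in 23 the effects had opposite signs. Many of these genes were named for a large change in either mutant or for this difference, so their share is not a measure of how common such differences are; over all genes 2265 of 21588 differed. Values are the log2 difference, lsm5 effect minus lsm4 effect. Mutant, accession, age and medium change together here, so none of these differences can be assigned to the mutant.

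The negative differences were AT5G24820 -10.31, AT1G29090 -9.48, AT4G28140 -7.92, AT3G27970 -6.95, M17 -6.91, BMY1 -6.01, FSD1 -4.43, DIC2 -4.05, CBF2 -3.87, AT4G36850 -3.14, JAZ10 -2.98, HSP18.2 -2.55, AOC1 -2.54, LSM4 -2.29, PR5 -1.88, AOS -1.82, JAZ5 -1.69 and SAG13 -1.45. Scaled over all 12 libraries, BMY1 stood at 15.1 CPM in WT Col, 2552 in lsm4, 3.32 in WT C24 and 8.81 in lsm5. The positive differences among genes of the fixed lists were PORC 1.02, CHE 1.41, SPL9 1.42, PORB 1.80, KIN1 1.96, FLS1 1.98, PAD3 2.04, FLC 2.28, LHCB1.2 2.61, MYB111 2.68, FUL 2.71, COR15B 3.70, GOLS2 4.28, PDF1.2A 5.10 and AP1 10.22. The other positive ones were Sadhu4-2 4.92, AT5G03350 5.46, AT5G41830 5.66, ATNIG1 7.47, AT3G22235 7.57, PCC1 7.64, ATCEL2 8.18, ACD6 8.21, CYP706A3 8.86 and AT2G20870 9.07. ACD6 stood at 138 CPM in WT Col, 0.435 in lsm4, 94.7 in WT C24 and 88.9 in lsm5. Where a group was at or near 0, as for AT5G24820, AP1 and ATNIG1, the size depends on the prior count.

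Among the gene lists, 5 differed by camera: jasmonate response downward (adjusted p = 3.6e-04) and photosynthesis (adjusted p = 7.4e-06), SR splicing factors (adjusted p = 0.049), root markers (adjusted p = 0.030) and floral organ markers (adjusted p = 0.0018) upward. With an estimated correlation their p was 0.024, 0.20, 0.54, 0.11 and 0.053, and none passed after adjustment. Of 100 regroupings of the libraries within accession, 4 gave as many genes as the 2265 of the real grouping, itself included. The highest other regrouping gave 4136 genes; it kept the real Col groups and exchanged the C24 groups as a whole. The regroupings that kept the real Col groups all gave at least 1055 genes, so the small share rests largely on breaking up the lsm4 effect, and chance is not excluded for the difference between the mutants.

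The first pattern weighed was the rise of intron reads in lsm4. Genomic DNA would add reads alike to introns of weakly and strongly expressed genes; the gain was 28.4 times larger in the highest than in the lowest tertile of host expression (95% interval 20.8 to 39.5), which argues against it. A single factor that multiplies the reads of all introns would move introns of a gene alike in log2. Within 1694 genes, introns without G at +5 rose less than those with it, by -0.271 in log2 (95% interval -0.330 to -0.212). The same difference in lsm5 was -0.140 (95% interval -0.192 to -0.0868). Only introns past the count filter entered, and reads in the lsm4 libraries could carry introns of low wild-type signal past it. The median log2 change in lsm4 depended on the filter, at 0.65 in the main fit and 0.43 at a mean count of at least 30. Whether introns with and without G at +5 passed the filter alike was not checked, so this test cannot decide on a single factor. A gain of equal density in all introns of a gene would raise log2 less where the wild-type signal was higher. Wild-type signal was not matched, so this test cannot decide on such a gain. Less splicing of some introns, slower decay of unspliced RNA and more nuclear RNA in the libraries may each contribute and were not told apart by any test here.

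The second pattern was that WT C24 2 and lsm5 3 lay between the genotypes on the first component and at opposite ends of the second. If their labels had been exchanged, WT C24 2 would carry the raised introns; over the 856 introns raised in lsm4, the lowest lsm5 library stood 0.887 in log2 above the highest WT C24 library, against an SD of 0.123, which argues against an exchange. On the main axis of variation within groups, gene length had a Spearman rho of 0.0525 across genes, against a length bias, and exon GC content a rho of -0.234, which leaves a GC bias open; genes are not independent replicates. That axis held 61.5% of the variance within groups, and across 19110 genes it followed the corresponding axis of the lsm4 comparison, on which WT Col 1 and lsm4 2 stood apart (rho 0.719). A difference in growth, age or handling between plants may also lie behind it and was not tested.

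The third pattern was the reads in LSM4 introns 5 to 7 in lsm4. None of 604 words of 25 bases from them occurred elsewhere in the genome (0%), which argues against reads from another copy. The density gain of intron 5 lay at percentile 96.0 of all tested introns, with 455 of 11439 gaining more, which leaves the general rise open by that measure; by ratio it rose by 4.16 in log2, with the lowest p of all tested introns (edgeR quasi-likelihood test, adjusted p = 1.9e-07), against a median change of 0.65. The density of at most 0.337% in introns 1 to 4 rests on at most 8 reads per library and was not part of that test. Introns 1, 3 and 4 had a lower density in lsm4 than in WT Col, intron 4 at 0.337 ± 0.193% against 2.08 ± 0.324%. Intron 2 had no read in WT Col and stood at 0.0572% in lsm4. By these few reads, the rise did not extend over all introns of LSM4. A transcript started or altered within the gene by the insertion or lesion of the mutant is a candidate explanation that was not tested, since the labels give no position.

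For the calls within a comparison, the 10 splits of 6 libraries are too few for a share under 0.05. In lsm4 the real split gave 4458 genes, 2065 introns, 13 AS bins and 3 lists, and the highest other split 0, 1, 1 and 8; the number of splits with as many was 1, 1, 1 and 7. In lsm5 the real split gave 486 genes, 38 introns, 0 AS bins and 3 lists, and the highest other split 4146, 505, 1044 and 6; the number with as many was 2, 2, 10 and 9. The split with 4146 genes set WT C24 1, WT C24 3 and lsm5 3 against WT C24 2, lsm5 1 and lsm5 2, which points to a structure of these samples that crosses genotype.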

How the results depend on the processing

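The surrogate variable, leaving out both libraries that stood apart and setting the median intron change to 0 were chosen after seeing the data. No named result that was called reversed, though the direction of some uncalled lists, of SEN1 in lsm4 and of 1 intron feature in lsm5 turned. Among all 2065 introns called in lsm4, 40 changed sign with library sizes in place of the host offset. For counts that moved by more than 1.5 times the cause was not tested, except where fewer features or samples show it.

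DESeq2 gave 51 AS bins in lsm4 (13 by edgeR), 1486 genes, 146 introns and 16 AS bins in lsm5 (486, 38 and 0), a difference in 3411 genes (2265), overlaps of 261 higher genes, 166 lower genes and 87 higher introns (92, 40 and 27), and 2 features of raised introns in lsm5 (0). Limma voom gave 3 introns in lsm5. Library sizes in place of the host offset gave 3584 introns (2065) and 212 AS bins in lsm4 and 107 introns in lsm5. No filter on low counts gave 49 AS bins in lsm4, 205 introns in lsm5 and 107 shared introns. A mean count of at least 30 tested fewer introns and gave 507 in lsm4 and 7 in lsm5. A median change set to 0 gave 570 and 7. At an adjusted p under 0.01 the overlaps were 6, 3 and 0.

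Whether replicate numbers pair the samples was not settled. Deviations from the group means correlated across genes at -0.275, -0.130 and 0.405 between same-numbered libraries in the lsm4 comparison. In the lsm5 comparison they correlated at -0.262, 0.521 and 0.479. Pairs with unlike numbers reached 0.439 and 0.537. A replicate block gave 3583 genes (4458), 1570 introns and 0 AS bins in lsm4, 1342 genes and 232 introns in lsm5, 2178 genes for the difference, overlaps of 176, 91 and 135, and 3 and 4 lists. A block by the tags in the descriptions, over the libraries whose tag occurs in both groups, gave 7445 genes, 3771 introns and 216 AS bins in lsm4 and 1630, 143 and 6 in lsm5. In lsm4 this also left out WT Col 1 and lsm4 2; leaving them out without a block gave 6563 genes and 3007 introns.

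A surrogate variable, estimated from the data it then corrects, gave 8317 genes and 90 AS bins in lsm4, 4566 genes, 408 introns and 71 AS bins in lsm5, and overlaps of 753 and 812 genes and 260 and 2 introns. Leaving out both libraries that stood apart widens the gap between groups by construction; it gave 123 AS bins (101 higher, 22 lower) in lsm4, and in lsm5 7901 genes (3795 higher, 4106 lower), 1230 introns (880 higher, 350 lower) and 937 AS bins (397 higher, 540 lower), so the lsm5 introns were less one-sided than the 37 higher and 1 lower called with all libraries. Gene lists passing camera (3 in each mutant) were 0 with an estimated correlation in both and 1 with fry in both. Features of raised introns (7 in lsm4) were 4 within the highest, 6 within the middle and 4 within the lowest tertile of intron count, and 2 in lsm5 within the highest tertile; the other tertiles in lsm5 held too few raised introns to give a value.

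With each library left out in turn, lsm4 gave 2704 to 4552 genes, 956 to 2647 introns and 0 to 16 AS bins, and lsm5 gave 23 to 2042 genes, 0 to 184 introns and 0 to 0 AS bins. The difference ranged from 1368 to 2832 genes, the overlaps from 6 to 230 and 0 to 129 genes and from 0 to 109 and 0 to 0 introns, and the lists from 3 to 4 in lsm4 and 3 to 3 in lsm5.

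Over all settings, 1739 of 2012 values of 135 named genes kept their side of the threshold, as did 451 of 538 for introns and AS bins, 339 of 358 for lists and 52 of 64 for features. Single libraries unsummed, the first or second library of a replicate alone, and 24 libraries in the interaction were not run, since the count columns hold both libraries together. Small changes were mostly missed: 2-fold changes were recovered in 12.5% of simulated cases in lsm4 genes and 10.6% in lsm5 genes.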
